A study of Homo sapiens with 8 samples.

How the data were processed

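Gene expression was measured by RNA sequencing in 8 libraries of human cells labelled as pulmonary artery smooth muscle cells, 4 given spent medium of vehicle-treated endothelial cells and 4 given spent medium of erastin-treated endothelial cells, each for 48 hours. Groups and replicate numbers were taken from the sample titles and treatment labels. The deposited table holds raw read counts per Ensembl gene, per the file headers, for 62710 genes, each an Ensembl gene ID joined to a symbol. The values are whole numbers with a different total in each library. The aligner, the counting program, the strand setting, the genome build and the annotation release are not given in the sources used here, so no coordinates are printed. Each column was matched to its sample through the library code in the sample description. The 2 columns of group means in the table were not used. Symbols and IDs are those of the table, and 20930 rows carry the ID in place of a symbol. For a list gene whose symbol stood on more than 1 row, the row with the most counts was used.

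Depth ran from 11284372 counts (control medium replicate 3) to 34019724 counts (control medium replicate 2). In pairs of replicates the counts differed by far more than sampling noise (chi-square per degree of freedom at least 9.56), so no library was counted as a duplicate. Intervals and floors cover counting error only. CPM values are counts per 1000000 of a library's total, without a scaling factor, and their errors are SD over 4 libraries. Log2 fold changes are ferroptotic medium minus control medium. Folds are 2 to that power, and can differ slightly from the ratio of the CPM means because of the scaling factors. The standard error of a log2 fold change is its size divided by the square root of the F statistic, an approximation.

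The main test was edgeR 4.0.16 in R 4.3.3. It used filterByExpr by group with a minimum count of 10, which kept 14608 genes, TMM scaling, glmQLFit with robust estimation and glmQLFTest with group as the sole term. Adjusted p are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Of the tested genes 4287 had an unadjusted p under 0.05. The common biological coefficient of variation was 0.154, and the median log2 fold change 0.02. Gene lists (29, with 596 genes) and the rule for the genes the text names were fixed before the data were examined. Camera in limma 3.58.1 compared each list of at least 5 tested genes with all other tested genes at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists tested. The lists' median, mean and camera direction differed in sign for BMP targets, mitochondrially encoded genes, immediate early genes and epithelial markers, none of them called.

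The lists cover contractile smooth muscle, extracellular matrix, matrix proteases and inhibitors, inflammatory cytokines and chemokines, NF-kB targets, interferon-stimulated genes, complement, receptors of danger signals with the inflammasome, NRF2 targets, ferroptosis and iron handling, and the ATF4 and amino acid response. They also cover chaperones of the endoplasmic reticulum, heat shock, metallothioneins, proliferation, p53 targets, cholesterol and fatty acid synthesis, BMP targets, TGF-beta targets, hypoxia and glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, and growth factors and receptors of pulmonary vascular remodelling. Markers of endothelial cells, fibroblasts, pericytes, leukocytes and epithelium complete them.

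Named genes were of 3 kinds. The first were the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, an average of at least 2 CPM, a symbol, and groups that did not overlap. The second were up to 3 members of each list with the smallest p among those past the threshold, or the member with the smallest p, given as values, where none passed; some of these are left out of the text, and 1 is not reported here. The third were 20 genes fixed by name, from ACTA2 and MYH11 to BMPR2 and NOTCH3. For the 59 named genes that passed and were followed through the alternatives, the groups did not overlap, which the rule itself sets for the 20 largest changes. SMURF2 and KRT18 also passed but were not followed, and their groups overlapped. SMURF2 was at 352.6 CPM in control medium replicate 4 and 352.9 CPM in ferroptotic medium replicate 1. KRT18 was at 110.9 CPM in control medium replicate 4 and 111.2 CPM in ferroptotic medium replicate 2, though both genes were called lower.

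Library size, mitochondrial share, ribosomal protein share, genes detected and the share of the 10 most abundant genes were compared by an exact two-sided permutation test over all 70 assignments, adjusted over these 5 measures. The alternatives tried were DESeq2 size factors, upper-quartile factors and library totals alone in place of TMM. Others were no filter beyond 1 count in any library, a filter of 1 CPM in at least 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom with and without quality weights, edgeR without robust estimation, and a replicate block. Lists were also tested with an estimated correlation, with fry and with cameraPR. Each of the 8 libraries was left out in turn. A fit without control medium replicate 1 and ferroptotic medium replicate 2 was added after seeing the data.

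The pipeline was tested on simulated counts drawn from the means and library sizes of this comparison, with 200 genes changed. Over 14447 simulated genes edgeR recovered 14%, 44%, 82% and 93.8% of genes changed 1.25-, 1.5-, 2- and 4-fold, and 4.96% of its calls were false. DESeq2 and limma-voom had 21.2% and 5.88% false calls in the same simulation. Exon overlap between genes was taken from GENCODE release 29 by Ensembl ID, for the lineage lists, ribosomal protein and proteasome genes (without 5 proteasome subunits of testis, thymus or interferon response), and IPO4 and IRF9. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.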

Results

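RNA sequencing measured gene expression in 8 human cultures labelled as pulmonary artery smooth muscle cells (PASMC), the contractile cells of the vessel wall. The cells had received spent medium from pulmonary artery endothelial cells, the cells that line the vessel, for 48 hours. The endothelial cells had been treated with vehicle (control medium, 4 cultures) or with erastin (ferroptotic medium, 4 cultures). Erastin blocks the cystine and glutamate exchanger whose transport subunit is encoded by SLC7A11, and sets off ferroptosis, an iron-dependent death by lipid peroxidation. The libraries held 11284372 to 34019724 counts, and 14608 genes had enough counts to be tested. Mean library size was 24921012 ± 9976208 counts after control medium and 25032647 ± 4349120 counts after ferroptotic medium (SD, n = 4 per group).

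The series asks how material released by ferroptotic endothelial cells alters gene regulation in PASMC, and the comparison of the media addresses it only in part. It cannot tell released material from erastin carried over in the medium. Nor does it show that the cells were PASMC, since the libraries carried endothelial markers at high levels. After ferroptotic medium, genes of cell division fell and genes of amino acid synthesis and import rose. All 30 tested proliferation genes were lower, with a median log2 fold change of -1.99, and 23 of 29 genes of the ATF4 and amino acid response were higher, with a median of 1.07 and none lower. HMOX1, the haem oxygenase that NRF2 induces under oxidative stress, rose 3.92-fold from 327.6 ± 13.0 to 1319 ± 237.7 CPM (counts per 1000000 of the library total, SD, n = 4). Of the 14608 genes, 2064 (14.1%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 887 higher and 1177 lower. At least 2-fold changes were fewer and mostly falls, with 78 genes higher and 235 lower.

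The balance of rises and falls depended on scaling: with library totals alone 1111 genes were higher and 935 lower. Leaving out control medium replicate 1 and ferroptotic medium replicate 2, which stood apart from their groups on the second principal component, left 1342 changed genes, 484 higher and 858 lower, of which 1245 were among the 2064. In that fit all 30 proliferation genes were lower and 26 of the ATF4 list higher. Leaving out ferroptotic medium replicate 3 left 1226 changed genes. The groups did not overlap for 1979 of the 2064 genes, and over all tested genes 21.2% were separated in this way against 2.86% by chance.

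The proliferation list held genes of DNA replication, mitosis and its control. RRM2, a subunit of the ribonucleotide reductase that makes DNA precursors, fell 8.28-fold from 121.8 ± 19.8 to 15.1 ± 1.09 CPM (log2 fold change -3.05 ± 0.12 SE, adjusted p 2.04e-07 in edgeR). MKI67, which encodes the Ki-67 proliferation antigen, fell 5.51-fold from 179.4 ± 54.2 to 33.2 ± 7.46 CPM (log2 -2.46 ± 0.26, adjusted p 7.40e-04). UBE2C, which acts in the degradation of mitotic cyclins, fell 5.72-fold to 6.54 ± 0.51 CPM, and BIRC5, a chromosomal passenger protein, fell 4.52-fold from 52.7 ± 7.29 CPM. The list was lower than the other tested genes by camera, limma's competitive set test (adjusted p 4.65e-160 at the preset correlation, adjusted p = 0.0060 with an estimated correlation), but not with an estimated correlation and a replicate block together (adjusted p 0.069). All 30 members also passed when adjusted over the list alone. The 10 largest falls among genes of at least 2 CPM were MYBL2 (10.7-fold), RRM2, AURKB (7.24-fold), EXO1 (6.83-fold), CDK1 (6.30-fold), CENPM (6.07-fold), KIF18B (6.05-fold), PCLAF (6.03-fold), PKMYT1 (5.81-fold) and UBE2C. MYBL2 is a transcription factor of the cell cycle, AURKB and CDK1 are mitotic kinases, and EXO1 is a DNA repair exonuclease.

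The ATF4 list held the 3 largest rises among genes of at least 2 CPM, SLC6A9, PHGDH and PSAT1. ATF4 is the transcription factor that stress kinases raise when amino acids run short or the endoplasmic reticulum is loaded. SLC6A9, a glycine transporter, rose 16.5-fold from 0.69 ± 0.23 to 12.7 ± 2.75 CPM (log2 4.05 ± 0.23, adjusted p 2.17e-06 in edgeR). PHGDH and PSAT1 encode the first enzymes of serine synthesis. PHGDH rose 11.8-fold from 9.91 ± 1.77 to 122.1 ± 17.6 CPM (adjusted p 7.32e-07) and PSAT1 rose 7.56-fold from 49.4 ± 6.81 to 383.1 ± 21.7 CPM (adjusted p 1.15e-07). ALDH1L2, a mitochondrial folate enzyme, rose 6.22-fold, and ASNS, asparagine synthetase, rose 4.14-fold from a low 1.11 ± 0.22 CPM. CHAC1, which degrades glutathione and rises in cells starved of cystine, rose 3.29-fold from 7.18 ± 0.55 to 24.3 ± 3.07 CPM. The list was higher by camera (adjusted p 1.64e-62, adjusted p = 0.0040 with an estimated correlation), and 28 of its 29 tested members were higher when adjusted over the list alone.

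Among the 10 largest rises, JDP2 (6.26-fold), PAPPA2 (6.19-fold), ADM2 (6.09-fold), VLDLR (4.66-fold) and OPLAH (4.01-fold) completed the set with SLC6A9, PHGDH, PSAT1, ALDH1L2 and ASNS. JDP2 is a transcription factor of the AP-1 family, PAPPA2 a protease that cleaves insulin-like growth factor binding proteins, ADM2 a vasodilator peptide, VLDLR a lipoprotein receptor and OPLAH a glutathione cycle enzyme. The VLDLR call was lost when control medium replicate 1, 2, 3 or 4 or ferroptotic medium replicate 3 was left out, with adjusted p from 0.054 to 0.070, without a low count filter (0.067) and with the replicate block (0.108). The JDP2 call was lost without control medium replicate 4 (adjusted p 0.050) and with the block (0.083), and its log2 fold change of 2.65 became 3.26 without control medium replicate 1.

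**Figure D1:**
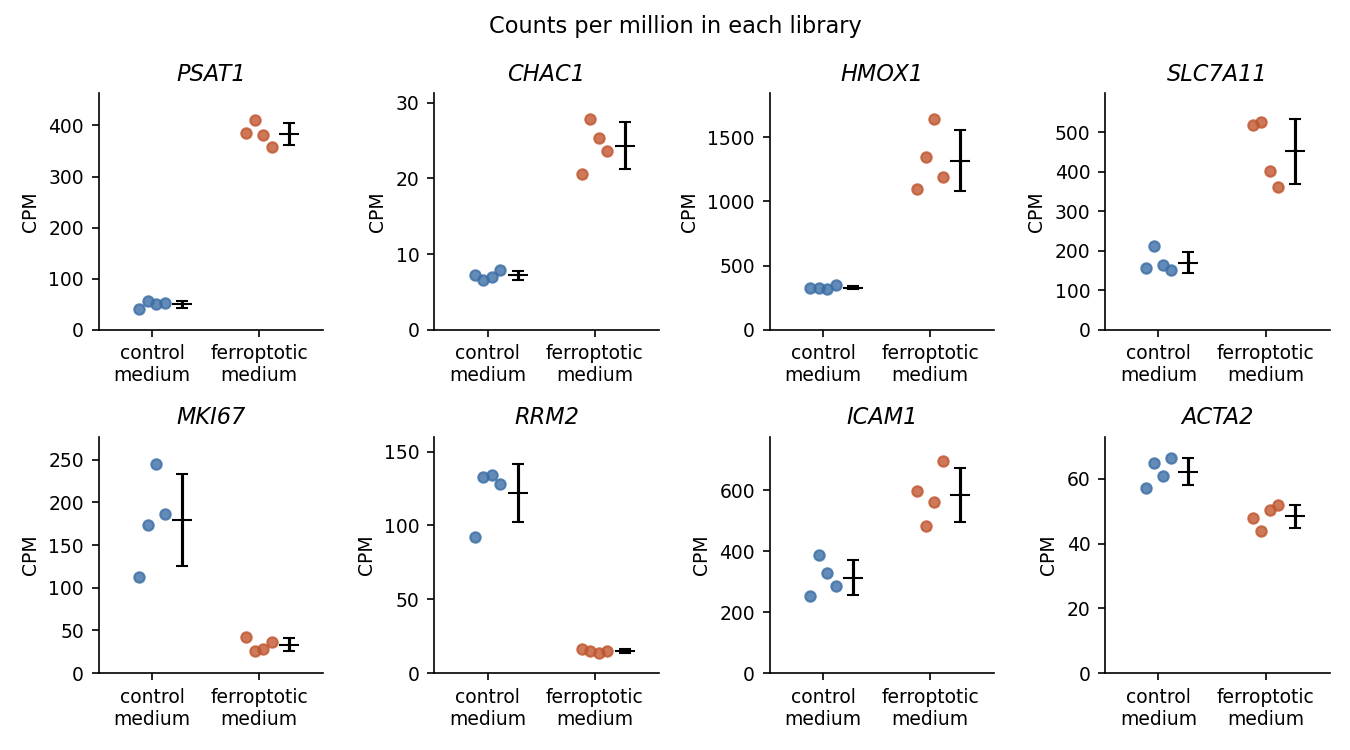
CPM (linear axis from 0) of 8 genes in each of the 8 libraries, with control medium in blue and ferroptotic medium in orange; black bars are the mean ± SD (n = 4). HMOX1 lay at 327.6 ± 13.0 CPM after control medium and 1319 ± 237.7 CPM after ferroptotic medium, and the groups did not overlap for any of the 8 genes.

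Targets of NRF2, the transcription factor of the antioxidant response, rose in part. Of 25 tested members 10 were higher and none lower, with 12 higher when adjusted over the list alone and a median log2 fold change of 0.28. Beside HMOX1 (log2 1.97 ± 0.12, adjusted p 2.39e-06 in edgeR), SLC7A11 rose 2.59-fold from 170.0 ± 27.6 to 451.6 ± 82.6 CPM, and TXNRD1, thioredoxin reductase, rose 1.52-fold from 1178 ± 136.1 to 1834 ± 180.3 CPM. FTH1, the ferritin heavy chain that stores iron, rose 1.87-fold from 2228 ± 319.8 to 4275 ± 715.1 CPM. FTH1 has several near-identical pseudogenes that can share its reads, so its level is uncertain. The list was higher by camera (adjusted p 3.61e-07), but not with an estimated correlation (adjusted p = 0.30).

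In the list of ferroptosis and iron handling 8 of 26 tested members were higher and 1 lower, both over all genes and when adjusted over the list alone. Of the 8 higher genes 5, among them SLC7A11, CHAC1 and FTH1, are also members of the NRF2 or ATF4 list. The other 3, named here after their values were seen, were AIFM2, GCH1 and SLC39A14, which act in radical trapping, tetrahydrobiopterin synthesis and metal import. GPX4, the peroxidase that detoxifies lipid peroxides, had 189.8 ± 11.3 CPM after control medium and 190.5 ± 14.7 CPM after ferroptotic medium (adjusted p 0.82). The median of the list was 0.02 on the log2 scale. The list was called higher by camera (adjusted p 0.012), but not with an estimated correlation (adjusted p = 0.33) or without control medium replicate 3 (adjusted p 0.056).

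Inflammatory genes gave fewer calls. Of 21 tested NF-kB targets 4 were higher and none lower (5 when adjusted over the list alone); 1 of the 4 is the row with the symbol SOD2, whose Ensembl ID is not the usual one of that gene. ICAM1, a leukocyte adhesion molecule, rose 1.82-fold from 312.6 ± 58.2 to 582.6 ± 88.2 CPM (log2 0.86 ± 0.14, adjusted p 0.0030 in edgeR), and TNFAIP2 rose 1.54-fold. The list was called higher by camera (adjusted p 0.0043), but not with an estimated correlation (adjusted p = 0.69). Of 18 inflammatory cytokines and chemokines 2 were higher, CSF1 (1.36-fold) and CSF2 (2.72-fold, from 0.93 ± 0.44 CPM), or 3 when adjusted over the list alone, and the list was not called (adjusted p 0.077), though it was without control medium replicate 2 (2.66e-05), ferroptotic medium replicate 3 (0.028) or 4 (0.031), without a low count filter (0.038) and with the replicate block (0.0049, but 0.58 with an estimated correlation as well). Both calls were lost without control medium replicate 3 or 4, with adjusted p of 0.066 and 0.060 for CSF1 and of 0.073 and 0.078 for CSF2. The CSF2 call was also lost without control medium replicate 1 (0.088) or ferroptotic medium replicate 2 (0.055), and the CSF1 call without ferroptotic medium replicate 3 (0.067). IL6 had 30.1 ± 12.5 and 42.7 ± 18.0 CPM after control and ferroptotic medium, CXCL8 430.4 ± 166.1 and 526.3 ± 105.7 CPM, CCL2 48.2 ± 19.0 and 63.0 ± 5.27 CPM, and C3 82.2 ± 62.2 and 150.3 ± 132.1 CPM. None of these 4 passed the test (adjusted p 0.40 to 0.57).

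Interferon-stimulated genes had a median log2 fold change of 0.34, but 3 of 31 were higher and 1 lower, also when adjusted over the list alone. IFIT2 rose 1.92-fold (lost without both libraries that stood apart, adjusted p 0.062) and STAT2 1.38-fold, while USP18, which dampens interferon signalling, fell 1.26-fold with adjusted p 0.029. The USP18 call was lost with library totals alone (adjusted p 0.058) and without control medium replicate 2 (0.053) or ferroptotic medium replicate 1 (0.054), 2 (0.063) or 3 (0.064). The list was called by camera (adjusted p 0.0029), but not with an estimated correlation (adjusted p = 0.85), by fry (adjusted p 0.28), without control medium replicate 4 (adjusted p 0.056) or without both libraries that stood apart (0.090). Of 18 receptors of danger signals and inflammasome genes 3 were higher and 1 lower (4 and 1 when adjusted over the list alone). CASP4 (log2 0.33 ± 0.06) and CASP1 (log2 0.59 ± 0.14), caspases of the inflammasome, were among the higher ones, and the list was not called (adjusted p 0.35). The CASP1 call was lost without control medium replicate 1 (adjusted p 0.051) or ferroptotic medium replicate 1 (0.058) or 3 (0.060). Of 14 complement genes 1 was higher, the complement regulator CD46 (1.18-fold), whose call was lost (adjusted p 0.052 to 0.090) when any library but control medium replicate 1 or ferroptotic medium replicate 4 was left out. The complement list was not called (adjusted p 0.64).

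The lists of contractile and lineage markers gave the levels of the cell types. ACTA2, smooth muscle actin, fell 1.32-fold from 62.2 ± 4.14 to 48.5 ± 3.52 CPM (adjusted p 0.0051 in edgeR), and SMTN, smoothelin, fell 1.39-fold from 399.2 ± 30.4 to 294.3 ± 34.7 CPM. Of 15 tested contractile genes 3 were lower and 1 higher, also when adjusted over the list alone. The list was not called (adjusted p 0.35), but was lower without ferroptotic medium replicate 2 (adjusted p 0.014). TAGLN had 349.1 ± 331.3 and 310.6 ± 346.4 CPM and CNN1 4.66 ± 4.60 and 2.89 ± 3.87 CPM after control and ferroptotic medium. TAGLN reached 836.8 CPM in control medium replicate 1 and 827.6 CPM in ferroptotic medium replicate 2, against 251.3 CPM or less in the other 6 libraries. MYH11, the smooth muscle myosin, had 0 counts among 199814635, which allows up to 0.015 CPM over the 8 libraries by counting error alone. RPS18 and RPS25, ribosomal protein genes looked up after the data were seen, were also under 1 CPM in every library, so a value near 0 in a single gene does not show that it was silent. NOTCH3, a receptor of mural cells, had 1.67 ± 0.95 and 1.14 ± 1.02 CPM.

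In the same libraries, labelled PASMC, endothelial markers stood at high levels in both groups. PECAM1, an adhesion molecule of endothelial junctions, had 1761 ± 174.1 CPM after control medium and 1532 ± 45.4 CPM after ferroptotic medium, and CDH5, the cadherin of those junctions, had 911.2 ± 38.5 and 793.1 ± 65.4 CPM. Of the 16 endothelial genes 14 had at least 10 CPM in every library and 11 at least 100 CPM. Of the 24 contractile genes 10 had at least 10 CPM in every library, 5 had at least 100 CPM, and 7 had under 1 CPM in every library. Of 10 pericyte genes 6, and of 12 fibroblast genes 7, had under 1 CPM in every library; MCAM and ANPEP, the 2 pericyte genes of at least 10 CPM in every library, are also made by endothelial cells. COL1A1, the main collagen of fibroblasts and smooth muscle cells, had 3.08 ± 1.26 and 2.44 ± 2.39 CPM. COL1A2, its partner chain, was higher, at 33.7 ± 17.1 and 26.2 ± 26.1 CPM. Of the 27 extracellular matrix genes 13 had at least 10 CPM in every library and 3 had under 1 CPM in every library. Of 15 tested endothelial genes 1 was lower, EGFL7 (1.28-fold), also when adjusted over the list alone, and the list was not called (adjusted p 0.089), though it was lower without control medium replicate 2 (0.011), ferroptotic medium replicate 3 (0.04996) or 4 (0.032), without a low count filter (0.012) and by fry (0.048). The EGFL7 call was lost without ferroptotic medium replicate 2 (adjusted p 0.051) or 3 (0.053). PECAM1, CDH5, MCAM, ANPEP and COL1A2 were named after their values were seen.

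**Figure D2:**
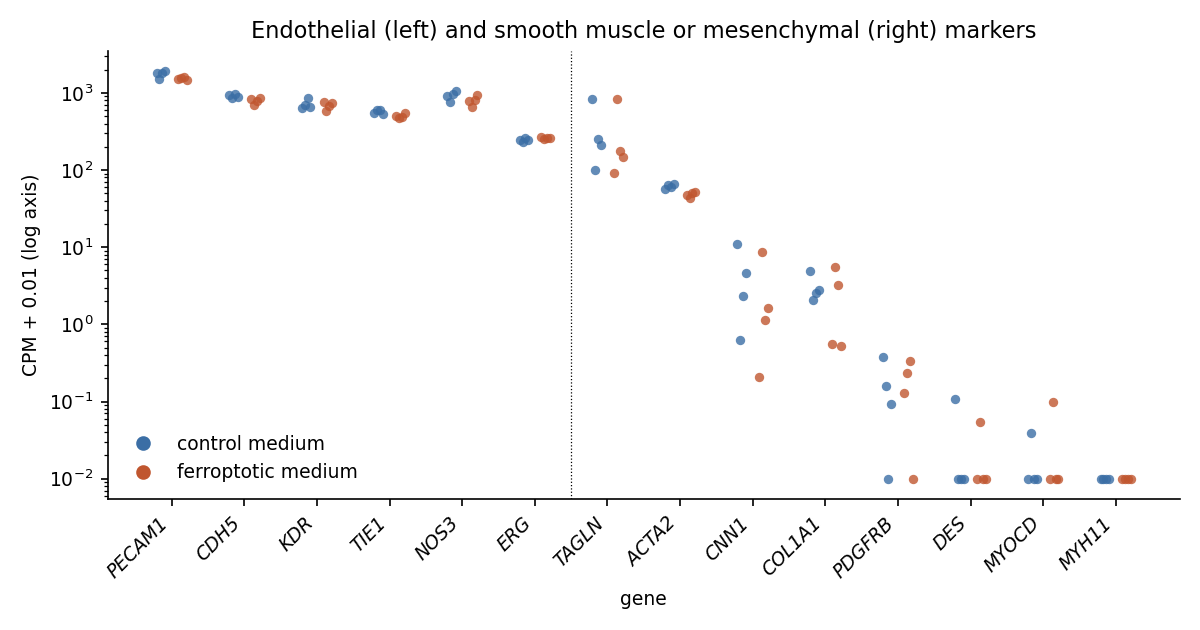
CPM + 0.01 (log axis) of 6 endothelial markers, left of the dotted line, and 8 smooth muscle or mesenchymal markers, right of it, in each of the 4 control medium libraries (blue) and the 4 ferroptotic medium libraries (orange). PECAM1 lay between 1475 and 1913 CPM in the 8 libraries, and MYH11 was at 0 in each. The genes shown are a selection, and NOS3 is not a member of the endothelial list. Contractile genes at high levels are not shown, such as FLNA (1265 to 1813 CPM) and CALD1 (287.4 to 441.7 CPM). Nor are endothelial genes at low levels, such as PLVAP (0.29 to 2.53 CPM) and ECSCR (at most 0.099 CPM), so the contrast looks sharper than in the whole lists.

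Of the lists of mitochondrial energy metabolism and matrix turnover, only nuclear oxidative phosphorylation was called. Of 26 nuclear-encoded genes of oxidative phosphorylation 7 were lower and none higher (11 lower when adjusted over the list alone), among them CYC1 (1.39-fold) and SDHB (1.30-fold). The list was called lower by camera (adjusted p 7.56e-04), but not with an estimated correlation (adjusted p = 0.69). None of the 13 mitochondrially encoded genes passed in edgeR or DESeq2, and 0 had an unadjusted p under 0.05 (list adjusted p 0.83). PLAU and PLAT, the plasminogen activators, fell 1.95-fold and 1.53-fold, from 70.1 ± 7.28 to 36.8 ± 5.66 CPM and from 2113 ± 79.2 to 1413 ± 184.6 CPM, and the collagenase MMP1 rose 1.67-fold. Of 15 matrix proteases and inhibitors these were the 3 that passed, with 1 more lower when adjusted over the list alone. None of 24 extracellular matrix genes passed in edgeR, where 2 had an unadjusted p under 0.05, and DESeq2 called 2 lower. The matrix list was not called (adjusted p 0.39), but was lower without ferroptotic medium replicate 2 (adjusted p 0.0010) and without both libraries that stood apart (0.0496). FN1, fibronectin, had 9810 ± 1382 and 10371 ± 2864 CPM.

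Other lists held single changes and were called under some alternatives or not at all. Of 27 hypoxia and glycolysis genes 4 were higher and 5 lower (5 and 6 when adjusted over the list alone), and VEGFA, the endothelial growth factor, rose 2.38-fold from 22.6 ± 2.68 to 55.6 ± 8.23 CPM (adjusted p 4.53e-05 in edgeR). EDNRB, the endothelin B receptor, rose 1.83-fold from 8.42 ± 2.07 to 15.8 ± 2.90 CPM, and EDNRB and VEGFA were the 2 higher genes among 22 growth factors and receptors of vascular remodelling. Of 26 genes of cholesterol and fatty acid synthesis 4 were lower and 1 higher, with ACAT2 down 1.72-fold and SCD up 1.34-fold (SCD lost without control medium replicate 4 or ferroptotic medium replicate 1, adjusted p 0.054 and 0.055). That list was called lower without ferroptotic medium replicate 4 (adjusted p 0.031), by fry (0.048) and without a low count filter (0.016). Of 22 p53 targets 4 were lower and 1 higher (6 and 1 when adjusted over the list alone), with BAX and DDB2 down 1.34-fold and 1.33-fold, and fry called the list lower (adjusted p 0.016). CDKN1A, the p21 inhibitor of the cell cycle, had 258.3 ± 9.54 and 227.5 ± 18.9 CPM (adjusted p 0.066), and passed as lower in 3 of 19 other settings. Of 17 chaperones of the endoplasmic reticulum 3 were lower and 1 higher (5 and 1 when adjusted over the list alone), with SDF2L1 down 1.71-fold and PDIA4 down 1.27-fold, and the list was called lower without control medium replicate 3 (adjusted p 0.022), ferroptotic medium replicate 2 (0.015) or a low count filter (0.016). Of 20 TGF-beta targets 1 was higher, CDKN2B (1.48-fold), and 2 lower, among them TGFB1 itself (1.26-fold), and the list was called lower without ferroptotic medium replicate 2 (adjusted p 0.0077). Of 11 BMP targets 1 was higher, HEY1 (2.42-fold, from 1.16 ± 0.18 CPM), and of 15 immediate early genes 2 were higher, among them EGR1 (1.52-fold), and 1 lower. BMPR2, the receptor mutated in heritable pulmonary hypertension, had 223.1 ± 32.9 and 239.7 ± 29.1 CPM (adjusted p 0.73), and ID1, a BMP target, 58.1 ± 15.7 and 49.4 ± 14.6 CPM (adjusted p 0.51).

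The remaining lists served as checks for other cells and stresses. Of 14 heat shock genes 1 was higher and 2 lower, of 5 tested leukocyte markers 1 was lower, CORO1A (1.81-fold, to 2.56 ± 0.59 CPM), and of 5 tested epithelial markers 1 was lower. None of the 5 tested fibroblast markers passed in edgeR or DESeq2, and 0 had an unadjusted p under 0.05. The 4 tested members of each of the metallothionein and pericyte lists were too few for a list test, and none passed over all genes, though 2 metallothionein-list members were higher when adjusted over the list alone. SLC30A1, a zinc exporter of the metallothionein list, had a log2 fold change of 0.41 ± 0.14 SE (adjusted p 0.081), and passed as higher in 2 of 19 other settings. In all, 7 of 27 tested lists were called at the preset correlation, and 2 of them, proliferation and the ATF4 and amino acid response, with an estimated correlation.

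**Figure D3:**
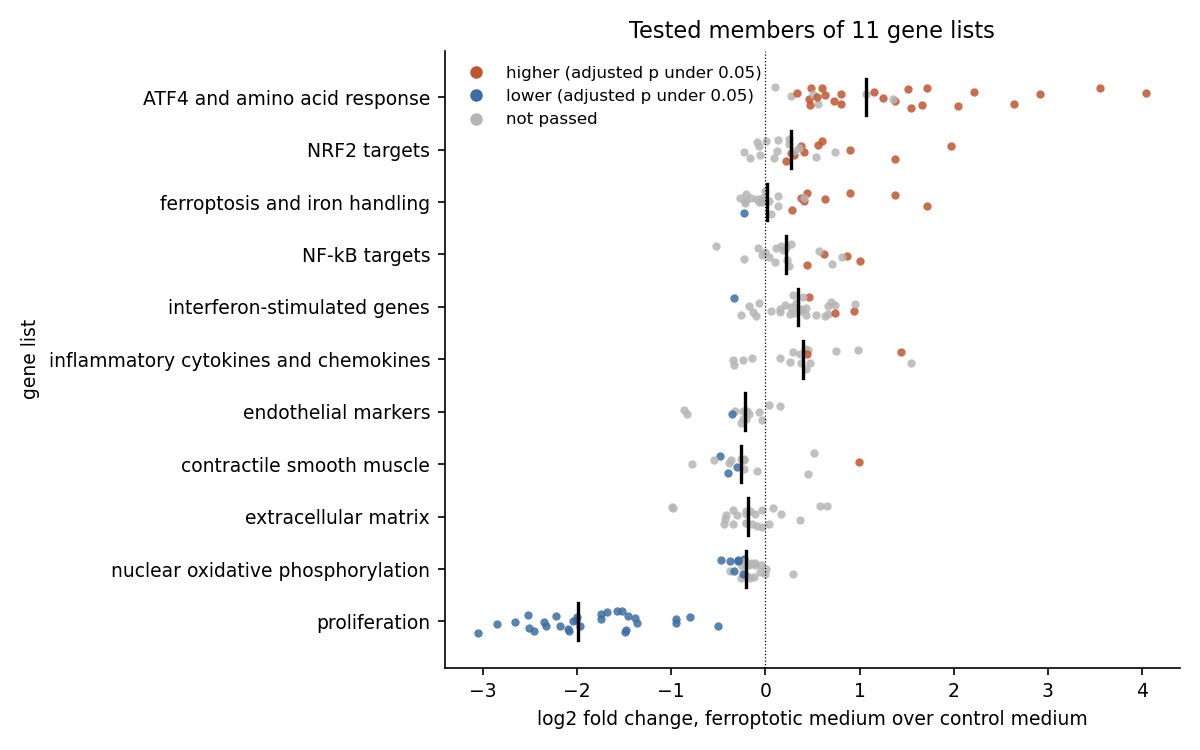
Log2 fold change, ferroptotic medium over control medium (horizontal axis), of each tested member of 11 gene lists (vertical axis). Orange and blue points passed an adjusted p of 0.05, grey points did not, and black lines mark list medians. The proliferation list (median -1.99) and the ATF4 list (median 1.07) lie apart from the others.

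Of 5 sample-level measures the ribosomal protein share came nearest to separating the media. Mitochondrial counts were 4.45 ± 0.43% and 4.65 ± 0.58% of each library after control and ferroptotic medium (exact permutation p 0.60, two-sided, n = 4 per group), and ribosomal protein genes took 3.50 ± 0.09% and 3.26 ± 0.10% (exact permutation p 0.057, adjusted over 5 measures 0.29). Library size, genes detected and the share of the 10 most abundant genes gave exact permutation p of 1, 0.77 and 0.46, where 70 assignments allow no p below 0.029, so a single measure cannot pass after the adjustment. Nothing in the labels says that the 4 cultures of a group came from separate donors or experiments, so p-values measure the spread between these cultures, which may be technical.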

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

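All tests in this part were chosen after the results they bear on were seen, except the share of exons that overlap another gene, whose bound was set before its value was computed.

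Libraries labelled PASMC carried endothelial markers at high levels, while 20 of 46 contractile, pericyte and fibroblast genes were under 1 CPM in every library. A minority of endothelial cells or RNA carried over with the medium would leave smooth muscle genes above endothelial ones, but the median of the endothelial list was at least 32.4 times that of the contractile list in every library. Near-total loss of reads in the counting is argued against as the cause for the whole set. Of 185 ribosomal protein and proteasome genes that most cells express, 5.95% were under 1 CPM in every library (95% interval 3.01 to 10.4%), against 43.5% of the 46 (28.9 to 58.9%). Loss to overlapping genes is argued against for the set too, since 75% of the 20 genes under 1 CPM shared under 10% of their exon length with another gene in GENCODE 29. That need not be the annotation used for counting, but with as little overlap 4.55% of 132 ribosomal protein and proteasome genes were under 1 CPM (1.69 to 9.63%), against 40.5% of 37 contractile, pericyte and fibroblast genes (24.8 to 57.9%). Most of these ribosomal protein and proteasome genes stood at far higher levels, so both comparisons find near-total loss only. RPS9, at 2.70 to 4.17 CPM, counted as kept. Partial loss, which could bring a gene of lower level under 1 CPM, was not tested. For a single gene such as MYH11 these shares do not decide between loss of reads and silence. That the sequenced cells may have been endothelial in all 8 libraries stays open as a hypothesis, since 87.5% of the endothelial list had at least 10 CPM in every library, with PECAM1 at 1475 CPM or more and MMRN1 at 1440 CPM or more. The design names no group that would set this, so no biological explanation was tested, such as smooth muscle cells that took on endothelial expression.

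The higher ATF4 and NRF2 targets and the lower proliferation genes were weighed against scaling, residual erastin and chance. Under 3 other scalings the ATF4, NRF2 and proliferation lists kept at least 100% of their numbers of called members. The choice among these scalings therefore does not account for the calls. They shifted log2 fold changes by a median of -0.0048, 0.020 and 0.038, far less than the medians of the ATF4 and proliferation lists, so those counts could hardly fall. All are computed from the same counts, so a change in the amount of RNA per cell was not tested. Erastin carried over in the transferred medium cannot be told apart from released material: CHAC1 rose by 1.72 on the log2 scale, as a block of cystine import could cause, and no library received erastin without endothelial cells. If the sequenced cells were endothelial and were the treated donors themselves, these changes would be a direct effect of erastin, which was not tested. Of the 35 ways to split the 8 libraries into 4 and 4, only the real one (1 of 35) gave as many changed genes, 2064 against at most 8. The same held for genes changed at least 2-fold, 313 against at most 7. This argues against chance for both counts but cannot exclude it, since 35 splits allow no share below 1 of 35. The other splits mix the media, so any real difference adds to the spread within their groups and lowers their counts. The effect of released material that the design names stays among the open explanations.

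The number of called lists does not exclude chance, since 23 of the 35 splits gave at least the 7 lists of the real one and the highest other gave 15. All 3 splits with 15 lists put control medium replicate 1 and ferroptotic medium replicate 2 on the same side, a structure of the samples. The real split gave the smallest p of the 35 for proliferation, the ATF4 and amino acid response, and ferroptosis and iron handling. For NRF2 targets 1 other split gave a p as small, for NF-kB targets 4, for nuclear oxidative phosphorylation 6 and for interferon-stimulated genes 16.

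Control medium replicate 1 and ferroptotic medium replicate 2 stood apart from their groups on the second principal component, which held 28.1% of the variance. Labels swapped between the groups would place them with the other medium, but the mean log2(CPM + 1) of the proliferation list left a gap of at least 1.32 to the nearest library of the other group. Depth is not the difference, since 0 of the 2 had the highest or lowest total of its group. Mesenchymal cells mixed into these cultures cannot be told apart from a change within the cells, as 33.3% of 9 tested fibroblast and pericyte genes were highest in both libraries, against 11.6% of all tested genes. Stronger TGF-beta target expression in both cultures is a candidate explanation (10 of 20 targets highest in both, percentile 100 among 10000 matched random lists). The percentile cannot decide it. Matrix and contractile genes such as COL4A1 and MYL9 weighed heavily on the component that set the 2 libraries apart. Random lists hold unrelated genes, so any list that varies together along it would rank high. Of 24 extracellular matrix genes 20, and of 15 contractile genes 8, were also highest in both. The TGF-beta list shares COL1A1, COL1A2, THBS1 and LOXL2 with the matrix list and TAGLN with the contractile list. TGF-beta can induce genes of those lists, so they do not show whether the pattern is specific to it. A batch or donor shared by the 2 cultures was not tested, as the labels give neither; their deviations from the group means correlated at 0.52.

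In groups of 4 a library far from the other 3 is found in about 1 in 20 groups by chance, which is 7.9 of the 158 groups examined here, and 12 were found. That rate holds for independent, normally distributed values. Genes of the same libraries vary together, so the 12 cannot be judged against the 7.9. Control medium replicate 1 held 6 of them and ferroptotic medium replicate 2 held 3. In control medium replicate 1, RRM2 was at 92.4 CPM against at least 128.3 in the other controls, AURKB at 19.2 against at least 32.0, CDK1 at 33.4 against at least 54.5 and BIRC5 at 41.9 against at least 55.3. BMPR2 was at 173.9 CPM in that library against at least 236.2, and SDF2L1 at 30.3 against at most 21.7. In ferroptotic medium replicate 2, TAGLN was at 827.6 CPM against at most 174.4 in the other 3, CNN1 at 8.63 against at most 1.61 and CSF2 at 4.76 against at most 2.06. MYBL2 was at 3.11 CPM in ferroptotic medium replicate 3 against at least 4.70, TXNRD1 at 1565 CPM in ferroptotic medium replicate 4 against at least 1902, and SMTN at 444.3 CPM in control medium replicate 3 against at most 389.4.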

How the results depend on the processing

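The fit without the pair of libraries that stood apart was chosen after seeing the data; the other settings were fixed before. No gene called in the main analysis and in another setting changed sign between them. The values give no sign that the replicate numbers pair the cultures (deviations of same-numbered libraries correlated at -0.50, -0.30, -0.20 and -0.24). The 2 libraries that stood apart can weigh on these correlations, so a weaker pairing is not excluded. Nor are cultures matched under other numbers: control medium replicates 1, 2, 3 and 4 correlated with ferroptotic medium replicates 2, 1, 4 and 3 at 0.52, 0.41, 0.39 and 0.25. That matching was picked after the correlations were seen. With the replicate block 790 genes passed, 777 of them among the 2064. The count ran from 1226 (without ferroptotic medium replicate 3) to 1821 with 1 library left out, and was 1342 without control medium replicate 1 and ferroptotic medium replicate 2; the other settings gave 1881 to 2593. Called lists numbered 2 with an estimated correlation, 1 with an estimated correlation and the replicate block together, 8 with the block alone, 9 by fry, 11 without a low count filter, and 6 to 11 with 1 library left out (11 without ferroptotic medium replicate 2), against 7. With the block and an estimated correlation the ATF4 list kept its call (adjusted p 0.041) and the proliferation list lost it (0.069), and fry did not call interferon-stimulated genes (0.28). The difference in library size, in units of 1000000 counts, was 0.11 and ran from -4.43 to 3.14 with 1 library left out, the first without control medium replicate 3. The difference in mitochondrial share was 0.20 percentage points and ran from 0.068 to 0.489 with 1 library left out.

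Of 74 named genes, scaling by library totals alone turned GPX4 (0.0055), and quality weights turned BMPR2 (-0.023). Both had missed the test, as had each gene that turned with 1 library left out: TAGLN ran from -1.39 to 0.70, CNN1 from -2.31 to 0.16, GPX4 from -0.10 to 0.012, BMPR2 from -0.031 to 0.12 and FN1 from -0.16 to 0.12. Without ferroptotic medium replicate 2, C3 went from 0.82 to 0.027, NOTCH3 from -0.64 to -1.44 and COL1A1 from -0.42 to -1.22 (-1.12 with limma-voom). Without both apart libraries FN1 (-0.076), IL6 (-0.0097), C3 (-0.091) and BMPR2 (-0.036) turned and 8 genes lost their call: IFIT2, CSF1, CSF2, CASP1, CD46, EGFL7, TGFB1 and CSRP1, with adjusted p from 0.057 (TGFB1) to 0.102 (CSF2). The block lost 15 calls: VLDLR, JDP2, USP18, CD46, CSRP1, CSF1, CASP4, SDF2L1, PDIA4, SCD, TGFB1, EGR1, EDNRB, EGFL7 and CORO1A, with adjusted p from 0.050 (TGFB1) to 0.112 (EGFL7). Leaving out 1 library lost 0 to 7. Calls were gained by CDKN1A, SLC30A1 and the matrix gene LOXL2, in 3, 2 and 1 of the 19 settings other than the main one. The cause of these changes was not tested. Small changes at low levels were seldom recovered in the simulation. Changes of 1.5-fold were recovered in 1 of 22 genes under 10 CPM and in 21 of 28 genes of at least 10 CPM. Changes of 2-fold were recovered in 6 of 15 and 35 of 35. The simulation changed 200 genes, against 2064 called in the data, and did not vary depth, so these shares need not hold for the data.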

Other observations

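Gene families set by symbol and chosen after the data were seen (11 families, adjusted together) covered replication, translation and protein turnover. They share members with the fixed lists: MCM2 to MCM7, CENPF and KIF11 with proliferation, and CARS1 and WARS1 with the ATF4 list. Their tests partly repeat those lists and are no separate support for them. Of 21 centromere proteins 19 were lower, and all 10 MCM and GINS genes of the replication helicase were lower, with a median log2 fold change of -1.42 (camera adjusted p 5.85e-35 and 1.10e-28, and with an estimated correlation 0.012 and 0.013). Of 10 tested Fanconi anaemia genes, which repair DNA crosslinks, 7 were lower, among them FANCD2 (log2 -1.57) and FANCA (-1.69). Of 31 kinesins 11 were lower and 3 higher: the mitotic motors KIF2C (-2.32), KIF20A (-2.05) and KIF11 (-2.00) were lower, and KIF1B, KIF3A and KIF21B were higher. With an estimated correlation the Fanconi and kinesin families both passed at 0.037. Under the other scalings each of these families had at least 6 lower members.

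Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher in 10 of 18 members and lower in 1, with a median of 0.33 (camera adjusted p 1.15e-07, 0.037 with an estimated correlation). GARS1 (log2 0.64, from 546.7 to 875.0 CPM), SARS1 (0.55) and EPRS1 (0.52) were higher, and KARS1 was lower (-0.27). Of 15 mitochondrial synthetases 2 were lower and none higher. Mitochondrial ribosomal proteins were lower in 18 of 72 members and cytosolic ribosomal proteins in 10 of 70, with none higher, but these families did not pass with an estimated correlation (0.083 and 0.27), and with library totals alone 10 and 8 members were lower. Of 33 proteasome genes 5 were lower and 1 higher, and of 11 histone genes 1 was lower. Of 5 tested ferritin heavy chain pseudogenes 4 were higher, with a median of 1.13 beside 0.90 for FTH1, whose reads they can share.

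MYL9, KRT7 and COL4A1 were picked from the genes that weighed most on the second principal component, which set 2 libraries apart. MYL9 reached 248.1 and 257.4 CPM, KRT7 278.9 and 229.4 CPM and COL4A1 313.0 and 360.8 CPM in control medium replicate 1 and ferroptotic medium replicate 2, in that order. In the other 6 libraries these genes had at most 73.1, 57.4 and 140.0 CPM. Some genes that most cells express were near 0 in all 8 libraries, such as IPO4 with 1 count and IRF9 with 10 counts in total, so a count near 0 can also come from how reads were assigned to genes, which the sources used here do not describe.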
